A study of Mus musculus with 18 samples.

How the data were processed

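Gene expression was measured by RNA sequencing in 18 libraries of mouse neonatal ventricular cardiac fibroblasts, 3 in each of 6 groups (si-NC, si-Foxm1, Ang-II, si-Foxm1+Ang-II, OE-NC and OE-Foxm1). Per the labels' protocols, RNA came from the mirVana kit, was kept at an RNA integrity number of 7 or more, and went into TruSeq stranded mRNA libraries from 4 μg of total RNA. Per the submitters' processing notes, the authors used fastp, HISAT2 and HTSeq with the mm39 mouse genome, and their versions and settings are not given in the sources used here. The deposited values are FPKM, fragments per kilobase of gene scaled to the total of the library, with 1 column per library and genes named by symbol. The gene annotation and gene lengths behind them are not stated. Groups and replicate numbers were taken from the sample titles, and 0 columns lacked a sample.

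FPKM is a count divided by a gene length and a library total, so whole counts and library totals were recovered from ratios between libraries. All 17960 genes above 0 gave whole counts within 0.02, and the method was checked on 4000 simulated genes. The recovered totals served as the depth of each library. A count of 0 allows up to 3 counts, which is 0.155 to 0.200 FPKM for a gene of 1 kb, and such limits cover counting error only. Differences between libraries of a group were compared with counting error over genes with a mean above 20 counts, which showed no duplicated library.

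Analysis ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. FPKM plus a pseudocount of 1 was put on the log2 scale without further scaling between libraries. The 12 libraries of the knockdown arm entered 1 limma fit with a mean per group, and the 6 overexpression libraries a fit of their own, each with eBayes and a mean-variance trend. Genes with a mean FPKM of at least 1 over the libraries of a fit were tested, p-values were adjusted by Benjamini-Hochberg over them, and genes with adjusted p under 0.05 were called. The comparisons were si-Foxm1 against si-NC, Ang-II against si-NC, si-Foxm1+Ang-II against Ang-II, the difference between the siRNA effects with and without angiotensin (the interaction), and OE-Foxm1 against OE-NC. Foxm1 was also compared between groups of 3 by a two-sided exact permutation test of FPKM.

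Pathway and cell type lists numbered 28, of which 25 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, again with its own estimated correlation, and adjusted by Benjamini-Hochberg within each comparison. Members were also adjusted over the list alone. Named genes were Foxm1, Usp10 and Mapk12, the 10 highest and 10 lowest called genes of each comparison whose groups did not overlap (chance separates 10% of genes in this way), the 5 highest and 5 lowest of the interaction, and up to 4 members with the smallest p of each list. The groups, comparisons, tests, lists, naming rule and the alternatives, except a voom fit, were chosen before the data were examined. Those alternatives were a pseudocount of 0.1, a filter at 0.1 FPKM or none, quantile normalization, median-of-ratios scaling, all 6 groups or only the compared groups in the fit, a block for the replicate number, a 2-fold minimum, the estimated correlation, and each library left out in turn. The voom fit on recovered counts was added after seeing the data.

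Correlations between comparisons are across genes. For the pair that shares the Ang-II libraries, 100 simulated draws of unchanged groups gave the correlation and covariance that sharing causes where no gene changes. Calls were tested on simulated data with 50 changed genes at each fold. At 2-fold, 98%, 98%, 96%, 94% and 96% were recovered in the order of the comparisons above, and at 1.25-fold 56%, 48%, 68%, 26% and 52%. Motifs of 7 bases were counted in the longest annotated 3′ UTR of each gene in GENCODE M21 (GRCm38), a different build from the authors'. UTRs of at least 50 bases and motifs in at least 50 genes were kept, which left 10696 of 11021 genes (97.1%) and 16080 motifs. For each motif, a z compared the log2 fold changes of genes with and without it, clipped at 1.5 and adjusted for UTR length and GC content by regression, and 100 permutations of the genes gave the largest z by chance. Counts-based tools that need raw counts from the authors were not used. Lists with fewer than 5 tested genes had no set test, and no library was left out of the main comparisons.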

Results

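RNA sequencing measured mRNA levels in mouse neonatal ventricular cardiac fibroblasts (NVCFs), the matrix-producing cells of the newborn ventricle. The 18 libraries fell into 6 groups of 3. Within the knockdown arm, cells received control siRNA (si-NC), siRNA against Foxm1 (si-Foxm1), the hypertrophic peptide hormone angiotensin II (Ang-II), or the Foxm1 siRNA together with the hormone (si-Foxm1+Ang-II). The overexpression arm held a control (OE-NC) and Foxm1 overexpression (OE-Foxm1). The labels do not say whether Ang-II cells also received control siRNA, nor which vector was used for overexpression.

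The table listed 18264 genes by symbol in FPKM, of which 17960 were above 0 in at least 1 library. Each library held between 14989001 and 19343344 counted fragments. The OE-NC libraries were the smallest, with 16384202 fragments at most, and every other library held at least 17450697. Between 15422 and 15878 genes were above 0 in a library. The 10 most abundant genes took 4.8% to 7.3% of the fragments. Libraries of one group differed by a mean chi-square of 1.69 to 5.46 over 12536 genes, where counting error alone gives 1. The highest values, 5.03 and 5.46, were those of Ang-II replicate 3 against its group. Fold changes are given on the log2(FPKM+1) scale with their standard error, 3 libraries against 3, and this scale understates changes of genes with low FPKM. FPKM levels are given as mean ± SD of 3 libraries.

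Foxm1, a forkhead transcription factor of the cell cycle, was lower in si-Foxm1 than in si-NC, lower in Ang-II than in si-NC, and far higher in OE-Foxm1 than in OE-NC. Its level was 10.1 ± 0.41 FPKM in si-NC and 5.97 ± 0.79 FPKM in si-Foxm1, a log2 fold change of -0.68 ± 0.10 (adjusted p = 4.33e-05). Ang-II cells held 4.64 ± 0.88 FPKM, which was -0.99 ± 0.10 against si-NC (adjusted p = 2.63e-06). Adding the siRNA to Ang-II left 3.31 ± 0.26 FPKM, or -0.38 ± 0.10 against Ang-II alone (adjusted p = 0.00452). Without Ang-II replicate 3 this last change was -0.25, its smallest size when any 1 library was left out. The difference between the knockdown effects with and without angiotensin was 0.30 ± 0.14 and did not pass the test (adjusted p = 0.345). In OE-Foxm1, Foxm1 reached 455 ± 49 FPKM against 16.6 ± 0.8 FPKM in OE-NC, a log2 fold change of 4.69 ± 0.07 (adjusted p = 3.37e-11). Fragments from an introduced cDNA cannot be told from those of the cell's own gene in this table. In each of these comparisons the 3 libraries of one group lay outside the range of the other, and the exact permutation test gave a two-sided p of 0.1, the smallest that 3 against 3 allows.

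**Figure D1:**
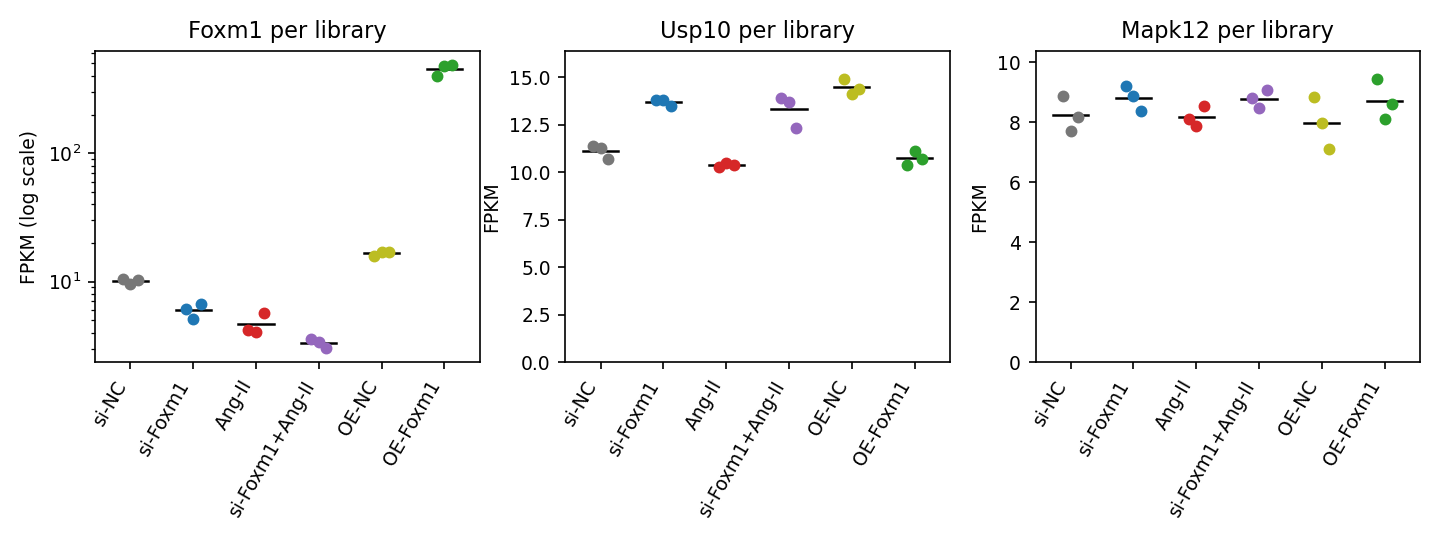
FPKM of Foxm1 (log axis), Usp10 and Mapk12 in each library of the 6 groups; each point is 1 library and each black line the mean of its group. Foxm1 lies between 3.03 and 17.1 FPKM in every group except OE-Foxm1, where it lies between 399 and 487 FPKM.

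Usp10, which encodes a deubiquitinase, and Mapk12, which encodes the p38 gamma kinase, were followed in every comparison. Usp10 was higher in si-Foxm1 (0.28 ± 0.04, adjusted p = 7.80e-05) and in si-Foxm1+Ang-II (0.32 ± 0.04, adjusted p = 2.53e-05) than in their controls, and lower in OE-Foxm1 (-0.40 ± 0.04, adjusted p = 2.22e-05). The OE-NC libraries held 14.1 to 14.9 FPKM of Usp10, OE-Foxm1 10.4 to 11.1 and si-NC 10.7 to 11.4. OE-NC was thus the group that stood apart from si-NC, although si-NC belongs to the other arm. Ang-II alone gave -0.09 ± 0.04 for Usp10 (adjusted p = 0.129). No comparison called Mapk12, whose log2 fold changes were 0.09 ± 0.05 with the siRNA (adjusted p = 0.145), -0.01 ± 0.05 with Ang-II (adjusted p = 0.879), 0.09 ± 0.05 with the siRNA under Ang-II (adjusted p = 0.127) and 0.12 ± 0.07 in OE-Foxm1 (adjusted p = 0.193). The siRNA effects with and without angiotensin differed by 0.04 ± 0.06 for Usp10 (adjusted p = 0.817) and by 0.01 ± 0.07 for Mapk12 (adjusted p = 0.987), and neither difference passed the test. Leaving out si-NC replicate 1 made the siRNA change of Mapk12 0.13 (adjusted p = 0.0378), and leaving out OE-NC replicate 1 made the overexpression change 0.19 (adjusted p = 0.0466). In a list of the p38 cascade that includes Usp10, 7 of 17 tested genes rose and 4 fell with the siRNA, and 7 rose and 4 fell with the siRNA under Ang-II. This balance followed the scaling, since median-of-ratios scaling and quantile normalization each gave 6 higher and 7 lower with the siRNA, and 6 higher and 5 lower with the siRNA under Ang-II. The kinases Map2k3 (0.34 ± 0.03 and 0.40 ± 0.03), Map2k4 (0.34 ± 0.03 and 0.35 ± 0.03) and Mapkapk2 (0.27 ± 0.03 and 0.33 ± 0.03) rose in both, in that order. As a set, these genes were not called with the siRNA (adjusted p = 0.857) or with the siRNA under Ang-II (adjusted p = 0.958). With Ang-II 1 rose and 8 fell (1 and 9 adjusted over the list alone), without a call as a set (adjusted p = 0.0671) except when genes down to 0.1 FPKM were included (adjusted p = 0.0479). Median-of-ratios scaling and quantile normalization each gave 1 higher and 5 lower with Ang-II. In OE-Foxm1 2 of 18 rose and 6 fell (2 and 5 adjusted over the list alone), and the set was not called (adjusted p = 0.575).

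The comparison of si-Foxm1 with si-NC asked what lowering Foxm1 changes in unstimulated NVCFs. Genes of heart muscle fell the furthest. Cardiomyocyte genes such as Actc1 were abundant in si-NC, and the labels name no sort that would remove cardiomyocytes. These values therefore do not tell which cells the falls came from. Tcap, which caps the giant sarcomere protein titin, fell by 2.95 ± 0.15, and Casq2, a calcium store protein of cardiac muscle, fell by 2.52 ± 0.07. Actc1, the cardiac actin gene, went from 2839 ± 147 to 605 ± 54 FPKM (-2.23 ± 0.05), and Nppa, the atrial natriuretic peptide gene, fell by 1.54 ± 0.05. At the other end, Mcpt4, a mast cell protease gene, rose by 2.90 ± 0.07, and the mitochondrial aldehyde dehydrogenase gene Aldh1b1 rose by 2.10 ± 0.06.

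Most called genes moved by less than 2-fold. Of 11180 genes tested, 7342 were called, with 5418 higher and 1924 lower in si-Foxm1, while 94 changed at least 2-fold, 51 up and 43 down. The median over all tested genes was 0.11, and the balance of directions followed the scaling. Under median-of-ratios scaling 6227 genes were called, 2954 higher and 3273 lower, and under quantile normalization 6395, 3426 higher and 2969 lower. The medians of gene lists are therefore given relative to the median of all genes of the same comparison, except for differences between the siRNA effects.

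S phase genes rose, and most mitosis genes did too. Of 33 DNA replication and S phase genes, 27 rose and none fell (28 rose when adjusted over the list alone; 24 rose and 2 fell under median-of-ratios scaling), among them the primase gene Prim1 (0.44 ± 0.06) and the helicase gene Mcm3 (0.43 ± 0.07). Their median was 0.26 above that of all genes, and camera called the list (adjusted p = 0.00532), but not with an estimated correlation (adjusted p = 0.794 with an estimated correlation). Of 35 mitosis and G2/M genes, 22 rose and 1 fell, with the same counts adjusted over the list alone. The spindle checkpoint gene Bub1b rose by 0.63 ± 0.07 and the spindle motor gene Kif11 by 0.49 ± 0.07. This list lay 0.15 above the median of all genes and was not called as a set (adjusted p = 0.244). Of 20 cell cycle inhibitor and DREAM complex genes, 10 rose and 2 fell, also adjusted over the list alone (5 and 5 under median-of-ratios scaling), without a call as a list (adjusted p = 0.983). One that fell was the cyclin-dependent kinase inhibitor gene Cdkn1a (-0.47 ± 0.06). With median-of-ratios scaling 15 of the mitosis genes rose and 3 fell.

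Markers of other cell types moved beside these groups. Among 18 cardiomyocyte markers, 16 fell and 1 rose (17 and 0 under median-of-ratios scaling), and among 11 macrophage and leukocyte markers all 11 fell, in both cases also when adjusted over the list alone. Relative to all genes, the cardiomyocyte median was -1.11 (adjusted p = 1.57e-15, and adjusted p = 0.119 with an estimated correlation) and the macrophage median -0.85 (adjusted p = 7.82e-09, and adjusted p = 0.119 with an estimated correlation). Lyz2, the macrophage lysozyme gene, fell by 0.89 ± 0.07 and Adgre1, which encodes F4/80, by 0.75 ± 0.08. Of 8 smooth muscle and pericyte markers 7 fell, as they did when adjusted over the list alone, such as Mcam (-0.43 ± 0.05; list adjusted p = 3.35e-04, and adjusted p = 0.119 with an estimated correlation). Endothelial markers went the other way in 6 of 10 cases, with 1 lower (also adjusted over the list alone), for example Cdh5 (0.52 ± 0.07), and were not called as a list (adjusted p = 0.642).

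Contractile and matrix genes were lower as well. Of 20 myofibroblast contractile genes, 15 fell and 2 rose, among them Acta2, the smooth muscle actin of activated fibroblasts (-0.64 ± 0.06), and Tpm1 (-0.72 ± 0.04). Of 30 collagen and structural matrix genes, 17 fell and 6 rose, with Eln, the elastin gene, at -0.56 ± 0.05 and Col12a1 at -0.58 ± 0.05. Of 26 matrix-modifying genes, 12 fell and 4 rose, and Lox, the collagen cross-linking oxidase, fell by 0.96 ± 0.06. All these counts were the same when adjusted over the list alone. Under median-of-ratios scaling 15 fell and 0 rose, 21 fell and 3 rose, and 18 fell and 2 rose, in that order. The myofibroblast list lay at -0.35 relative to all genes (adjusted p = 2.29e-07, and adjusted p = 0.263 with an estimated correlation). The collagen list lay at -0.23 (adjusted p = 3.00e-05, and adjusted p = 0.267 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.138). The matrix-modifying list lay at -0.19 (adjusted p = 6.72e-05, and adjusted p = 0.263 with an estimated correlation). Fibroblast markers fell in 4 of 13 cases and rose in 2 (list adjusted p = 0.00628, and adjusted p = 0.427 with an estimated correlation). That call ended under quantile normalization (adjusted p = 0.141). With median-of-ratios scaling 9 of these markers fell and 1 rose, and the camera call remained (adjusted p = 0.0294). As cardiomyocyte markers fell in the same libraries, these values do not tell which cells the contractile changes came from.

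Cholesterol synthesis, p53 target and unfolded protein response genes fell more often than they rose. Of 22 cholesterol synthesis genes, 18 fell and 1 rose, also when adjusted over the list alone. Sc5d fell by 0.64 ± 0.04, while Hsd17b7 rose by 0.51 ± 0.04. The list stood at -0.36 relative to all genes (adjusted p = 2.64e-09, and adjusted p = 0.263 with an estimated correlation). Of 22 p53 target genes 13 fell and 2 rose, and of 20 unfolded protein response genes 12 fell and 3 rose, with the same counts adjusted over the list alone. Ei24 (-0.70 ± 0.04) and Pdia6 (-0.40 ± 0.04) were among them (list adjusted p = 3.00e-05 and 7.98e-04, and adjusted p = 0.267 and 0.284 with an estimated correlation). Of 20 integrated stress response genes 4 rose and 4 fell, also adjusted over the list alone, but 0 rose and 11 fell under median-of-ratios scaling and 3 rose and 7 fell under quantile normalization. That list was not called (adjusted p = 0.0738) except under median-of-ratios scaling (adjusted p = 0.0226). Respiratory chain genes rose in 18 of 26 cases and fell in 1, also adjusted over the list alone, but under the same scaling 9 rose and 5 fell. Their camera call (adjusted p = 0.0378, and adjusted p = 0.844 with an estimated correlation) ended under that scaling (adjusted p = 0.584). In all, camera called 13 of 25 lists, and 0 of these calls held with an estimated correlation.

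Genes whose 3′ UTR holds either of a pair of short motifs were lower than other genes in this comparison. The motifs were TCCATTA or its neighbour CCATTAA, and AATAGGA or its neighbour ATAGGAA. Among 10696 genes with a 3′ UTR, the 7916 with neither motif had a mean log2 fold change of 0.13 (95% interval 0.12 to 0.14), and the 444 with both had -0.10 (95% interval -0.13 to -0.07). One or both motifs occurred in 26.0% of these genes and in 45.4% of the genes called lower. The motifs were chosen as the lowest of all motifs over the siRNA comparisons with and without angiotensin together, so these values describe that choice. The means are not adjusted for UTR length or GC content, and the intervals treat genes as independent. Casq2, Tpm1, Acta2, Sc5d, Ei24, Pdia6 and Mcam each carry a motif, whereas Actc1, Nppa, Tcap, Lox, Eln and Col12a1 carry neither.

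**Figure D2:**
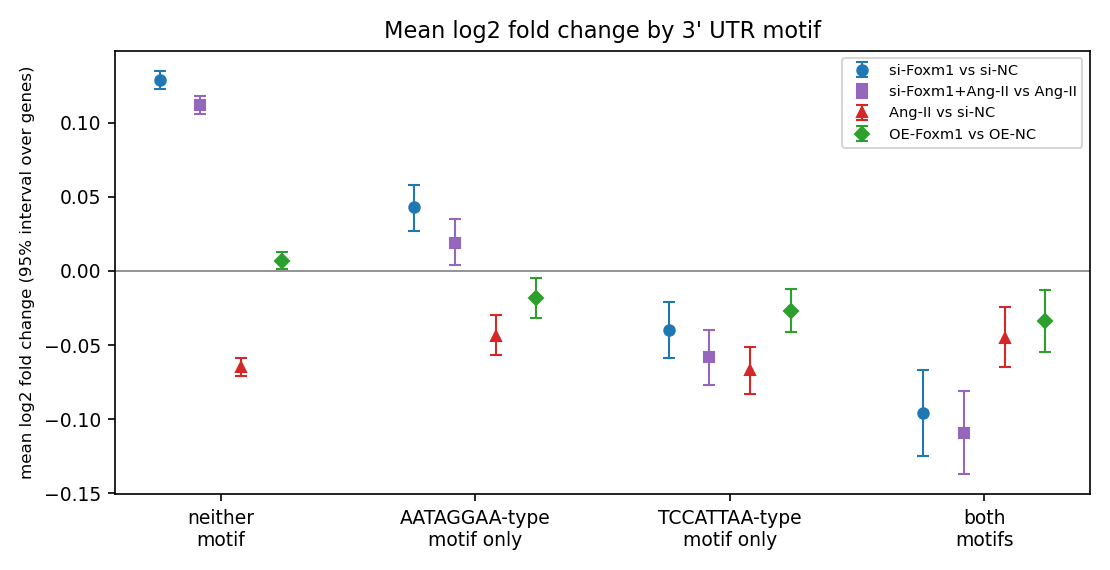
Mean log2 fold change by 3′ UTR motif class in 4 comparisons; points are means over genes and bars are 95% intervals. Genes with both motifs have a mean of -0.10 in si-Foxm1 against si-NC and -0.11 in si-Foxm1+Ang-II against Ang-II, while genes with neither have 0.13 and 0.11. The motifs were chosen for their low values in these siRNA comparisons.

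The comparison of Ang-II with si-NC asked how angiotensin II changes NVCFs. Matrix genes were among the strongest to rise. Ltbp2, a matrix protein gene placed in the TGF-beta pathway list, rose by 2.55 ± 0.08, from 2.26 ± 0.16 to 18.2 ± 2.6 FPKM. The fibrillar collagen gene Col11a1 rose by 1.68 ± 0.04, and Lox by 1.29 ± 0.06. Thy1, a fibroblast surface marker, fell by 2.01 ± 0.08, and Ecrg4, which encodes the secreted peptide augurin, by 2.33 ± 0.18. Of 11180 genes, 4970 were called, 1702 higher and 3268 lower, and 155 of them changed at least 2-fold, 44 up and 111 down. The excess of lower genes depended on the scaling, since median-of-ratios scaling gave 2481 higher and 2424 lower and quantile normalization 2673 higher and 2302 lower.

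Cell cycle genes fell together under Ang-II. All 33 tested S phase genes fell, as did 34 of 35 mitosis genes, with none higher in either list and the same counts adjusted over the list alone. Uhrf1 fell by 1.27 ± 0.09, Chaf1b by 1.07 ± 0.08, and the mitotic kinesin gene Kif20a by 1.09 ± 0.06. The mitosis median was -1.06 (adjusted p = 5.22e-21, and adjusted p = 0.232 with an estimated correlation) and the S phase median -0.71 (adjusted p = 2.33e-16, and adjusted p = 0.232 with an estimated correlation). Of 20 cell cycle inhibitor and DREAM complex genes 11 fell, also adjusted over the list alone, and 1 rose, the G1 kinase inhibitor gene Cdkn2b (0.62 ± 0.07). That list was not called (adjusted p = 0.0650) except under median-of-ratios scaling (adjusted p = 0.0422) and quantile normalization (adjusted p = 0.0475).

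Matrix genes split by member. Of 30 collagen and structural genes, 13 rose and 12 fell (14 and 13 adjusted over the list alone), with Col12a1 at 1.42 ± 0.05, Col1a1 at 0.88 ± 0.03 and Col5a2 between them. The list median was 0.10 (adjusted p = 0.0107, and adjusted p = 0.413 with an estimated correlation), and quantile normalization ended the call (adjusted p = 0.232). Of 26 matrix-modifying genes, 15 rose and 8 fell, also adjusted over the list alone, with Timp1 higher (0.80 ± 0.04) and Timp2 lower (-0.73 ± 0.04). That list had a median of 0.20 (adjusted p = 0.00160, and adjusted p = 0.251 with an estimated correlation). Fibroblast markers fell in 9 of 13 cases and rose in 2, also adjusted over the list alone. Tcf21, a fibroblast lineage factor, fell by 0.94 ± 0.08, while the microfibril gene Mfap4 rose by 1.90 ± 0.05. The marker list's call (median -0.47, adjusted p = 0.0306, and adjusted p = 0.415 with an estimated correlation) ended when genes down to 0.1 FPKM were included (adjusted p = 0.114).

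TGF-beta pathway genes rose in 12 of 25 cases and fell in 8, also adjusted over the list alone, with Ltbp3 higher (0.60 ± 0.03) and the inhibitory factor gene Id1 lower (-1.24 ± 0.07). Their median was 0.12 (adjusted p = 0.0140, and adjusted p = 0.232 with an estimated correlation), and the call ended under quantile normalization (adjusted p = 0.0811) and median-of-ratios scaling (adjusted p = 0.0524).

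Protein folding and amino acid stress genes rose. Of 20 unfolded protein response genes, 18 rose and none fell, also adjusted over the list alone, such as Hyou1 (0.46 ± 0.04) and the chaperone gene Hspa5 (0.34 ± 0.04). Of 20 integrated stress response genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone), with Nupr1 at 0.92 ± 0.06 and Trib3 at 0.66 ± 0.07. The medians were 0.23 (adjusted p = 5.22e-11) and 0.26 (adjusted p = 8.99e-06), and each list had an adjusted p = 0.232 with an estimated correlation. Respiratory chain genes fell in 25 of 26 cases with none higher, also adjusted over the list alone, such as Uqcrfs1 (-0.34 ± 0.03; list adjusted p = 1.61e-10, and adjusted p = 0.251 with an estimated correlation). The inflammatory genes Il6 (1.29 ± 0.14), Ptgs2 (1.14 ± 0.14) and Cxcl12 (0.89 ± 0.05) rose within a list of 16 in which 6 rose and 4 fell (6 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.161).

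Markers of other cells moved here too. Among 18 cardiomyocyte markers 17 fell and 1 rose, with a median of -0.42 (adjusted p = 2.58e-08, and adjusted p = 0.232 with an estimated correlation). Of 10 endothelial markers 8 fell and none rose, with a median of -0.33 (adjusted p = 0.00349, and adjusted p = 0.232 with an estimated correlation). Macrophage markers rose in 5 of 11 cases and fell in 1. These 3 counts were the same when adjusted over the list alone. The macrophage call (adjusted p = 0.0298, and adjusted p = 0.305 with an estimated correlation) ended under quantile normalization (adjusted p = 0.0596) and under median-of-ratios scaling (adjusted p = 0.0664). Camera called 13 of 25 lists for Ang-II, and 0 calls held with an estimated correlation. Since the control siRNA status of the Ang-II cells is unknown, a difference in transfection cannot be separated from the hormone.

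The comparison of si-Foxm1+Ang-II with Ang-II asked what the Foxm1 siRNA changes in stimulated cells. The same muscle genes stood at the bottom: Tcap fell by 2.78 ± 0.15 and Actc1 by 2.33 ± 0.05, with Casq2 between them. Proliferation genes rose, led by the topoisomerase gene Top2a, which went from 9.41 ± 1.6 to 18.9 ± 0.55 FPKM (0.94 ± 0.08). Aldh1b1 rose by 2.51 ± 0.06 and Mcpt4 by 2.50 ± 0.07. The matrix protein gene Tgfbi, induced by TGF-beta, fell by 0.95 ± 0.07. Of 11180 genes, 6860 were called, 4918 higher and 1942 lower, and 100 of them changed at least 2-fold, 47 up and 53 down. Median-of-ratios scaling gave 3082 higher and 3116 lower, and quantile normalization 3344 higher and 2880 lower.

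In the proliferation lists, 31 of 35 mitosis genes and 32 of 33 S phase genes rose and none fell, also adjusted over the list alone. Kif11 rose by 0.79 ± 0.07, Bub1b by 0.78 ± 0.07, Prim1 by 0.74 ± 0.06 and Mcm3 by 0.70 ± 0.07. The medians were 0.47 (adjusted p = 6.22e-06, and adjusted p = 0.511 with an estimated correlation) and 0.48 (adjusted p = 7.43e-07, and adjusted p = 0.423 with an estimated correlation). Cardiomyocyte markers fell in 15 of 18 cases and rose in 2, and all 11 macrophage markers fell, also adjusted over the list alone. Their medians were -0.96 (adjusted p = 8.06e-13, and adjusted p = 0.160 with an estimated correlation) and -0.92 (adjusted p = 1.32e-09, and adjusted p = 0.122 with an estimated correlation). Lyz2 fell by 1.30 ± 0.07 and Itgam, an integrin gene of myeloid cells, by 0.96 ± 0.06.

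Matrix and contractile lists were lower in these cells. Of 30 collagen and structural genes, 15 fell and 4 rose, of 26 matrix-modifying genes 11 fell and 3 rose, and of 20 myofibroblast genes 9 fell and 3 rose, all with the same counts adjusted over the list alone. Under median-of-ratios scaling 21 fell and 2 rose, 16 fell and 3 rose, and 15 fell and 2 rose, in that order. Loxl2 fell by 0.37 ± 0.05, Timp3 by 0.42 ± 0.04, Col6a2 by 0.45 ± 0.06 and Tpm1 by 0.68 ± 0.04, while Thbs1, the thrombospondin gene, rose by 0.53 ± 0.06. The list tests gave adjusted p = 8.56e-05, 0.00114 and 7.41e-04 in that order, and adjusted p = 0.348, 0.348 and 0.423 with an estimated correlation. The collagen call ended under quantile normalization (adjusted p = 0.167). For TGF-beta pathway genes, 8 rose and 10 fell of 25, also adjusted over the list alone. The median of that list was -0.08 and camera placed it lower (adjusted p = 0.0493, and adjusted p = 0.348 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.125), median-of-ratios scaling (adjusted p = 0.107) and the wider filter at 0.1 FPKM (adjusted p = 0.0617). Cholesterol synthesis genes fell in 18 of 22 cases and rose in 1, also adjusted over the list alone, with Stard4 at -0.60 ± 0.06 (list adjusted p = 2.85e-07, and adjusted p = 0.348 with an estimated correlation). Camera called 14 of 25 lists, and 0 calls held with an estimated correlation.

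The siRNA effects with and without angiotensin, measured in libraries that do not overlap, followed each other closely. Across 11180 genes, Pearson's r was 0.909 and Spearman's rho 0.882, where genes are not independent replicates. Both comparisons called 4366 genes higher and 1546 lower, against 2383 and 334 expected by chance overlap, while 10 genes went up then down and 10 down then up. Genes with both 3′ UTR motifs had a mean of -0.11 in stimulated cells (95% interval -0.14 to -0.08), and 47.7% of the genes called lower carried one or both motifs.

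**Figure D3:**
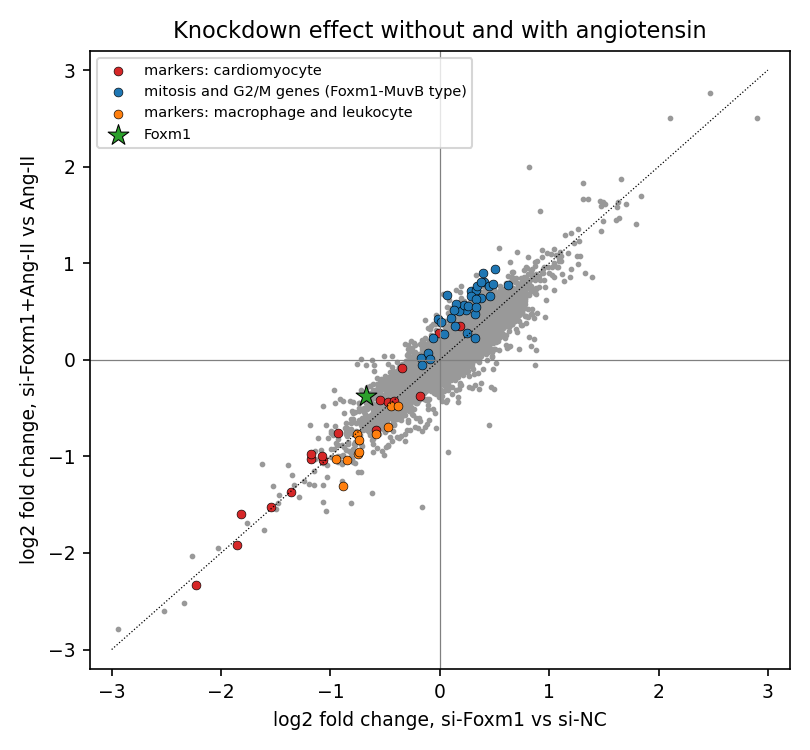
Log2 fold change of each gene in si-Foxm1 against si-NC (horizontal axis) and in si-Foxm1+Ang-II against Ang-II (vertical axis), with cardiomyocyte, mitosis and macrophage genes and Foxm1 marked. Pearson's r across 11180 genes is 0.909; cardiomyocyte markers reach -2.23 and -2.33 and mitosis genes lie mostly above 0.

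The test of the interaction asked where the siRNA acted differently in stimulated and in unstimulated cells. As the control siRNA status of the Ang-II cells is unknown, a transfection difference cannot be separated from it here, nor in si-Foxm1+Ang-II against Ang-II. Tgfbi held 5.41 ± 0.48 FPKM in si-NC and 5.73 ± 0.18 FPKM in si-Foxm1, but went from 18.2 ± 1.5 to 8.92 ± 0.72 FPKM with the siRNA under Ang-II, a difference of -1.03 ± 0.10 (adjusted p = 4.01e-04). St14, a membrane serine protease gene, differed by -0.76 ± 0.10 (adjusted p = 0.00239), and its level fell from 15.9 ± 1.5 to 5.46 ± 0.36 FPKM under Ang-II. Serpina3n, an acute phase protease inhibitor gene with close paralogs, differed by -1.13 ± 0.11 (adjusted p = 4.01e-04). In the other direction, Lox fell less under Ang-II (0.51 ± 0.08, adjusted p = 0.00991), and Scel differed by 0.65 ± 0.10 (adjusted p = 0.00946). Mitosis genes had a median difference of 0.30, with 3 of 35 called and 21 when adjusted over the list alone. Camera called that list (adjusted p = 5.20e-21), but not with an estimated correlation (adjusted p = 0.636 with an estimated correlation). S phase genes had a median difference of 0.22, with 0 of 33 called by limma and 3 when adjusted over the list alone (list adjusted p = 2.03e-12, and adjusted p = 0.636 with an estimated correlation).

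Of 11180 genes, 103 passed this test, 45 with a positive and 58 with a negative difference, although median-of-ratios scaling gave 67 and 48 and quantile normalization 73 and 65, and 1603 had an unadjusted p under 0.05. The count hung on single libraries: it was 45, 61 and 59 without si-NC replicates 1, 2 and 3, 40 and 64 without si-Foxm1 replicates 1 and 2, 196 without Ang-II replicate 3, and 37 and 56 without si-Foxm1+Ang-II replicates 2 and 3.

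The angiotensin effect and the siRNA effect under angiotensin were correlated across genes at r = -0.173 and rho = -0.196. They share the Ang-II libraries, and in 100 simulated draws where no gene changed that sharing alone gave a mean r of -0.503. As genes did change in the data, these values of r cannot be set against each other. The covariance was -0.0135 against -0.00198 in those draws, a difference of -0.0116. The draws used a spread pooled over the groups, while the Ang-II libraries differed most among themselves. The covariance due to sharing may therefore be understated.

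The comparison of OE-Foxm1 with OE-NC asked what raising Foxm1 changes. Chemokine genes rose the most after Foxm1 itself. Ccl2, which recruits monocytes, went from 26.5 ± 1.1 to 150 ± 18 FPKM (2.45 ± 0.07), Ccl7 rose by 2.55 ± 0.08, Ccl20 by 2.36 ± 0.06 and the neutrophil chemokine gene Cxcl1 by 2.21 ± 0.09. Heat shock and antioxidant genes were lower, with Hspa1a at -3.17 ± 0.09, Hspa1b, a near-identical paralog, at -2.91 ± 0.06, and the heme oxygenase gene Hmox1 at -1.92 ± 0.04. Of 11259 genes, 6200 were called, 3052 higher and 3148 lower, and 65 of them changed at least 2-fold, 34 up and 31 down.

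Of 22 chemokine, cytokine and NF-kB genes, 17 rose and 1 fell, also adjusted over the list alone. The gene that fell was Ptgs2, the inducible cyclooxygenase (-2.23 ± 0.08). Their median was 0.68 (adjusted p = 1.59e-07, and adjusted p = 0.440 with an estimated correlation). Macrophage markers rose in 7 of 11 cases and fell in 3, also adjusted over the list alone, with Adgre1 at 0.98 ± 0.07 and C1qb at -0.74 ± 0.07, and were not called as a list (adjusted p = 0.0688) except when genes down to 0.1 FPKM were included (adjusted p = 0.0201).

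S phase genes fell. Of 33 in the list, 30 fell and 1 rose, also adjusted over the list alone. Ccne2, the cyclin E2 gene, fell by 1.31 ± 0.04 and Mcm6 by 0.64 ± 0.03, while Gmnn, which encodes the replication licensing inhibitor geminin, rose by 0.74 ± 0.04. The list median was -0.38 (adjusted p = 2.26e-10, and adjusted p = 0.440 with an estimated correlation). Of 35 mitosis genes, 5 rose and 13 fell, also adjusted over the list alone, and the list was not called (median -0.05, adjusted p = 0.356). Among them Pttg1, the securin gene, rose by 0.72 ± 0.05 and Cenpa by 0.36 ± 0.04, while Prc1 fell by 0.44 ± 0.05.

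Cholesterol and matrix genes rose. Of 22 cholesterol synthesis genes, 20 rose and none fell, also adjusted over the list alone, such as Mvk (0.82 ± 0.05), Mvd (0.80 ± 0.05) and Lss (0.61 ± 0.04). The list median was 0.40 (adjusted p = 2.62e-11, and adjusted p = 0.440 with an estimated correlation). Of 30 collagen and structural genes, 16 rose and 4 fell, the same adjusted over the list alone, and of 26 matrix-modifying genes 15 rose and 4 fell (17 and 4 adjusted over the list alone). Lum, the lumican gene, rose by 1.24 ± 0.08, Dcn by 0.77 ± 0.04 and Mmp3 by more than either, while Tnc fell by 0.72 ± 0.05. The list tests gave adjusted p = 0.0226 and 0.0142, and adjusted p = 0.722 for both with an estimated correlation. The collagen call ended under quantile normalization (adjusted p = 0.0789). Immediate early and ERK feedback genes fell in 14 of 25 cases and rose in 5, also adjusted over the list alone, with Fosl1 at -1.72 ± 0.06 and Phlda1 at -1.02 ± 0.04 (list adjusted p = 0.0226, and adjusted p = 0.480 with an estimated correlation). Camera called 8 of 25 lists, and 0 calls held with an estimated correlation.

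The OE-NC libraries lay above si-NC in the stress genes Hspa1a and Hmox1. Hspa1a was at 36.1 ± 4.8 FPKM in OE-NC, 3.11 ± 0.38 in OE-Foxm1 and 1.41 ± 0.064 in si-NC, and Hmox1 was at 397 ± 19, 104 ± 3.5 and 63.5 ± 2.1 FPKM. All 31 genes at least 2-fold lower in OE-Foxm1 were nearer to si-NC in OE-Foxm1 than in OE-NC. OE-NC lay above si-NC in them by a median of 1.59. Of 33 genes at least 2-fold higher, Foxm1 left out, 7 were nearer. The OE-NC values themselves chose both sets, which tilts these counts, so they only describe the sets. For the lower genes, an effect of Foxm1 and a raised level in OE-NC cannot be told apart. The labels give no batch, so a batch between the arms cannot be separated from them.

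Across 11021 genes, the overexpression and knockdown effects were weakly opposed, with r = -0.128 and rho = -0.145. Genes raised by the siRNA and lowered by overexpression numbered 1721, against 1490 expected by chance overlap, and genes lowered and then raised numbered 730 against 519 expected. Genes raised by both numbered 1184 against 1457 expected, and genes lowered by both 443 against 531. Of the genes called in both comparisons, 39.9% thus moved the same way. All these counts rest on siRNA directions whose balance followed the scaling. Foxm1 itself is part of both effects.

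**Figure D4:**
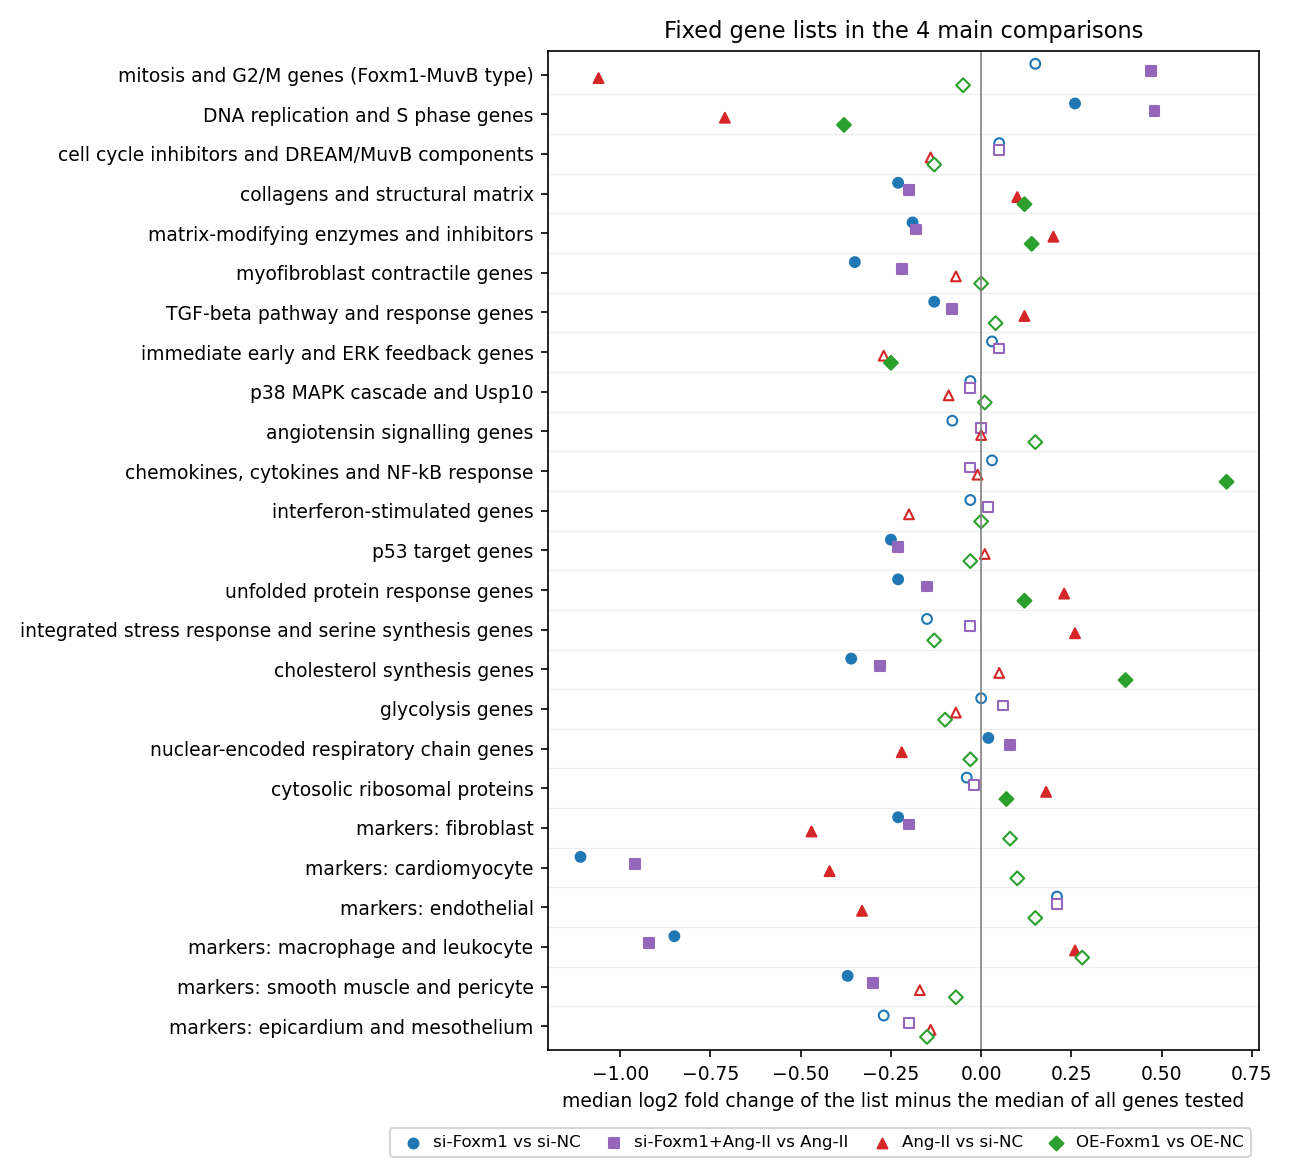
Median log2 fold change of each gene list minus the median of all tested genes in 4 comparisons; filled points are lists that camera called at its preset correlation. In si-Foxm1 against si-NC the cardiomyocyte list lies at -1.11 and the S phase list at 0.26, and in OE-Foxm1 against OE-NC the chemokine list lies at 0.68.

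The p-values here measure spread between libraries of a group, and the labels do not say whether these came from separate cultures or animals.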

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

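The counts over other splits of the libraries were read only after the results were seen; the interaction itself was among the comparisons chosen earlier. What brought each value here is a difference between the siRNA effects in stimulated and unstimulated cells that passed its own test. The interaction called 103 genes. Of the 100 splits of the 12 libraries counted, 4 gave as many genes, the real one included, and the highest other split called 8260 genes. Whether chance can be excluded for this count cannot be told from them, because splits that mix libraries across the large main effects widen the residual: its median SD was 0.122 over the other splits, against 0.0588 for the real one. The split with 8260 genes exchanged Ang-II with the combined treatment, which points to the structure of the samples, since its contrast adds the siRNA effects instead of subtracting them. The 4 splits that kept si-NC whole beside a single Ang-II library called 2889, 1722, 5 and 3 genes, and the cause was not tested. All other splits with a single Ang-II library in that place called 0. The next split after the real one called 32. Without 1 library the count ran from 37 (si-Foxm1+Ang-II replicate 2) to 196 (Ang-II replicate 3).

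The named genes among them encode proteins of the matrix, the cell surface and other places, with log2 differences from limma fits of 3 libraries per group. Tgfbi differed by -1.03 (adjusted p = 4.01e-04), Lox by 0.51 (adjusted p = 0.00991), Col11a1 by 0.33 (adjusted p = 0.0144) and the BMP decoy receptor gene Bambi by -0.53 (adjusted p = 0.00779). St14 differed by -0.76 (adjusted p = 0.00239), the keratin gene Krt18 by -0.69 (adjusted p = 5.78e-04), Scel by 0.65 (adjusted p = 0.00946) and Fxyd6 by -0.65 (adjusted p = 0.00159). Serpina3n differed by -1.13 (adjusted p = 4.01e-04), Serpinb1a by -0.61 (adjusted p = 0.0225), Aldh1b1 by 0.40 (adjusted p = 0.0268) and Slc52a3 by 0.52 (adjusted p = 0.0226).

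Reg3a differed by 1.18 (adjusted p = 4.01e-04) at 4.17 ± 0.024 FPKM or less in the knockdown arm, and Apol9a, which has close paralogs, by 0.65 (adjusted p = 0.0129). Reg3a lost its call with a pseudocount of 0.1 and with voom. Fxyd6, Serpinb1a, Aldh1b1 and Slc52a3 were not followed in fits without each library. Of 14 named genes refitted in this way, 10 kept their calls in every fit, Reg3a and Apol9a among them (highest adjusted p = 0.00280 and 0.0444), and 4 did not. The cholesterol exporter gene Abca1 differed by -0.93 (adjusted p = 0.0195), and lost its call without si-NC replicate 1, si-Foxm1 replicate 1 or si-Foxm1+Ang-II replicate 2 (highest adjusted p = 0.0608). Ube2c, an enzyme gene of mitotic exit, differed by 0.61 (adjusted p = 0.0216), and lost it without si-NC replicate 1 or 3, si-Foxm1 replicate 1 or 2, or si-Foxm1+Ang-II replicate 2 or 3 (highest adjusted p = 0.0667). Sprr2a3, at -1.36 (adjusted p = 0.0422), kept its call only without si-Foxm1 replicate 3, Ang-II replicate 2 or si-Foxm1+Ang-II replicate 1 (highest adjusted p = 0.114). Tcp11x2, at 0.62 (adjusted p = 0.0488), lost it in 9 of 11 such fits, those without si-NC replicate 1 or 3, any si-Foxm1 replicate, Ang-II replicate 1 or 3, or si-Foxm1+Ang-II replicate 2 or 3 (highest adjusted p = 0.128).

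Gene lists differed too, all without a call when camera estimated the correlation. Median differences were 0.30 for mitosis genes (adjusted p = 5.20e-21, and adjusted p = 0.636 with an estimated correlation), 0.22 for S phase genes (adjusted p = 2.03e-12, and 0.636 so estimated) and 0.14 for myofibroblast genes (adjusted p = 2.88e-08, and 0.636). They were 0.04 for matrix-modifying genes (adjusted p = 0.0130, and 0.636), 0.02 for integrated stress response genes (adjusted p = 0.0130, and 0.636) and 0.04 for cholesterol synthesis genes (adjusted p = 0.0221, and 0.837). Glycolysis genes gave 0.03 (adjusted p = 0.0405, and 0.720), respiratory chain genes 0.03 (adjusted p = 0.0492, and 0.856), cardiomyocyte markers 0.06 (adjusted p = 0.0130, and 0.720) and macrophage markers -0.18 (adjusted p = 0.0249, and 0.636). The respiratory and cardiomyocyte calls ended under quantile normalization (adjusted p = 0.375 and 0.948), and the respiratory and macrophage calls when genes down to 0.1 FPKM were included (adjusted p = 0.0523 for both). The respiratory call also ended with a pseudocount of 0.1 (adjusted p = 0.0568).

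For the comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. The real split called 7342 genes for the siRNA, 4970 for Ang-II, 6860 for the siRNA under Ang-II and 6200 for overexpression, and the highest other split called 0, 1, 0 and 0. In each of these comparisons 1 of the 10 splits, the real one, gave as many genes. Every other split mixes libraries of the groups compared, which widens the residual of genes that differ. Low counts there follow from that mixing and do not test chance.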

How the results depend on the processing

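The voom fit was chosen after seeing the data; the other alternatives were fixed earlier. The 5 counts of called genes kept within 1.5 times their value under the alternatives run, with these exceptions. Requiring a 2-fold change as well left 94 genes for the siRNA, 155 for Ang-II, 100 for the siRNA under Ang-II, 4 for the interaction and 65 for overexpression, since that rule drops the small changes. The interaction count was 57 without a filter, 169 with all 6 groups in one fit and 229 with voom, and the cause was not tested. With 1 library left out it ran from 37 to 196, and the other counts ran from 6666 to 6945, 4198 to 4953, 6143 to 6648 and 5506 to 5836. Similar counts do not mean that the same genes were called. Of 7342 siRNA calls, 4878 kept call and direction under median-of-ratios scaling and 5294 under quantile normalization. The numbers kept were 4126 and 3968 of 4970 for Ang-II, and 5024 and 5236 of 6860 for the siRNA under Ang-II. For overexpression they were 6136 and 5958 of 6200.

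The correlation between the siRNA effects was 0.895 with genes down to 0.1 FPKM, and 0.897 to 0.909 with 1 library left out; the cause was not tested. Foxm1 kept its direction and its side of the threshold in every comparison and alternative. One named gene turned: Vim, the vimentin gene, lower in si-Foxm1 by default, was at 0.068 under quantile normalization, and the cause was not tested. Of the other values for named genes under alternatives, 9228 kept direction and side, 160 lost a call and 71 gained one. For lists, 534 stayed, 77 lost a call and 14 gained one, and the estimated correlation ended all 58 list calls. Median-of-ratios scaling is not part of this tally of lists. It ended some list calls and made others, as given with the lists above. Replicate numbers were not taken to pair the libraries, since residuals of the same number correlated at -0.041 to 0.175 in the knockdown arm and 0.016 to 0.101 in the other. In the knockdown arm 7 of 18 pairs of the same number were over 0.1, against 2 of 36 of different numbers, so a shared origin of some libraries stays open. A block for the number gave 7411, 5008, 6945, 137 and 6210 genes. The smallest simulated changes were recovered least in the interaction (26%).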

Other observations

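The tests of the 3′ UTR motifs in the siRNA comparisons, of the cardiomyocyte markers and of the OE-NC state were chosen only after those results were seen; the tests of CCCCGTT in OE-NC against si-NC were chosen before their values were known.

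Among groups of genes not yet described, p53 targets in OE-Foxm1 split, with 6 higher and 8 lower of 22 (also adjusted over the list alone; list adjusted p = 0.615). Gdf15, a stress-induced growth factor gene, fell by 0.94 ± 0.03 and the kinase gene Plk2 by 1.04 ± 0.04, while Ei24 rose by 0.58 ± 0.04. Unfolded protein response genes rose in 11 of 20 cases and fell in 2, also adjusted over the list alone, such as Sdf2l1 (0.54 ± 0.06; list adjusted p = 0.0203, and adjusted p = 0.440 with an estimated correlation). In the integrated stress response list 11 of 20 genes fell and 4 rose, also adjusted over the list alone, with the cystine transporter gene Slc7a11 at -1.30 ± 0.08 and the serine synthesis gene Psat1 at -0.51 ± 0.03, and the list was not called (adjusted p = 0.0505), although it was with a filter at 0.1 FPKM (adjusted p = 0.0346), a replicate block (adjusted p = 0.0438) and median-of-ratios scaling (adjusted p = 0.0498).

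Among angiotensin signalling genes, Rcan1, a calcineurin regulator, fell with the siRNA alone and by 1.01 ± 0.06 with the siRNA under Ang-II, and rose by 0.23 ± 0.03 in OE-Foxm1. The regulators of G protein signalling Rgs4 (1.11 ± 0.13) and Rgs5 (0.66 ± 0.07) rose with Ang-II. Agtr1a, the angiotensin receptor gene, rose by 0.89 ± 0.08 with the siRNA at low levels (0.689 ± 0.11 to 2.13 ± 0.24 FPKM). Of 13 such genes tested, 5 rose and 3 fell with the siRNA, 3 rose and 4 fell with Ang-II, 6 rose and 2 fell with the siRNA under Ang-II, and 7 rose and 1 fell in OE-Foxm1, with the same counts adjusted over the list alone and no call as a list (adjusted p = 0.774, 0.710, 0.849 and 0.160). The siRNA counts followed the scaling, with 4 higher and 5 lower in both siRNA comparisons under median-of-ratios scaling.

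Genes with TCCATTA in the 3′ UTR were lower in both siRNA comparisons (z of -15.7 and -15.4), and so were genes with AATAGGA (z of -9.5 and -10.0), where 100 permutations of the genes reached 4.7 and 4.9 in size. Base composition is argued against for TCCATTA, which lay beyond the lowest other motif of the same bases by -8.5 or more, and stays open for AATAGGA, whose gap of -3.7 missed the bound of -4, a bound kept when the test was split by motif after its joint value was known. With Ang-II against si-NC, where no group held the Foxm1 siRNA, z was 0.0 and 1.8, and exon 8 of 8 of an annotated Foxm1 transcript, in the coding sequence (GRCm38 chromosome 6, 128373050 to 128373068, + strand), holds the 19 bases TTCCTATTCAGTCCATTAA, whose arrangement of TCCATTA and the reverse complement of AATAGGA occurs in 2 of 55341 genes, Foxm1 and Gm47477. A candidate explanation is that an siRNA of this sequence pairs with other mRNAs through the seeds of both strands, and the values it needs are present. The siRNA sequence is not in the labels, the motifs were found in the same data, and changes of genes without a motif may stem from Foxm1 or from secondary effects, which these tests do not separate.

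Cardiomyocyte markers were lower in both siRNA comparisons, from Actc1 at -2.23 and -2.33 to Pln at 0.18 and 0.35, and the labels name no sort that would remove cardiomyocytes, whose genes were abundant in si-NC (Actc1 2839 ± 147, Nppa 3473 ± 158, Myh6 1617 ± 105 FPKM). A smaller share of cardiomyocytes stays open: the markers fell unequally, with an interquartile range at least 17.4 times the median standard error, but how much of each the fibroblasts express was not measured, so unequal falls decide nothing. Motifs in the markers' own 3′ UTRs are argued against as the cause, since the 15 markers without a motif had a median log2 fold change of -0.76 or lower, and scaling is argued against, since the median log2 fold change stayed at -0.97 or lower under median-of-ratios scaling. A response of cardiomyocytes to lower Foxm1 or to other effects of the siRNA stays open too, and none of the 18 markers is in another list.

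Heat shock and NRF2 target genes were lower in OE-Foxm1 than in OE-NC (32 of 36 lower and 1 higher, median -0.56), counts that only describe the pattern, since the heat shock and NRF2 lists were written after it was seen, and chemokine, cytokine and NF-kB genes were higher (17 of 22). A stress state of the OE-NC libraries may account for the first group. OE-NC lay above si-NC there by a median of 0.77, and 91.7% of these genes were nearer to si-NC in OE-Foxm1 than in OE-NC. As the lists were written after the pattern was seen, that share describes these genes and does not test the state. In the chemokine group 22.7% were nearer, and OE-NC lay at a median of 0.10 against si-NC. These values show no sign of such a state there, but si-NC belongs to the other arm, so it is not excluded. Genes with CCCCGTT in the 3′ UTR were also lower in OE-NC, with z of 8.1 for OE-Foxm1 against OE-NC, -7.3 for OE-NC against si-NC and -1.7 for OE-Foxm1 against si-NC, so that a small RNA pairing with this motif in the OE-NC cells is a candidate explanation. Noise of the OE-NC libraries that these comparisons share is argued against, since each OE-NC library kept out of the first comparison gave z of -7.0 or lower alone against si-NC. The vector is not named in the labels, and an effect of Foxm1 on a stress state shared by both overexpression groups, and a batch between the arms, stay open.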
